A study of Mus musculus with 8 samples.

How the data were processed

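RNA from 2 pools of E12.5 mouse hearts, taken without the conotruncal region, and from 6 pools of E12.5 epicardial cultures was hybridized by the authors to Illumina mouse arrays, 1 array per pool of at least 3. Per the labels, cultures grew out for 3 days and were kept for 2 further days. The labels of the control and knockout cultures name whole hearts as their source, and the knockout culture carries no treatment; both were taken as cultures from their titles and the series design. The authors exported a non-normalized bead intensity and a detection p-value for each probe with BeadStudio 3.3. The lowest intensity on each array was above 0, so background had not been subtracted. The authors' processed values are a linear intensity that had been quantile-normalized in 2 sets of 4 arrays, as their identical distributions within each set showed: both hearts, the vehicle culture and the 3-factor culture in set 1, and the control, knockout and PDGF-BB cultures in set 2. The method is not given in the sources used here. The highest non-normalized intensity was 25863 to 27914 in set 1 and 45002 to 53266 in set 2, so the sets also differed before normalization.

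All values reported come from the non-normalized intensities. They were corrected for background with limma 3.58.1 in R 4.3.3 (neqc: a normal and exponential model whose background comes from the detection p-values, offset 16, then quantile normalization over all 8 arrays) and are on the log2 scale. The probe table used gave a single gene symbol for 34885 probes, several for 18 and none for 10378. Probes of the last kinds were counted apart: in the knockout hearts 32 of 2071 measured ones passed the rule of size, and in the knockout culture 97 of 2268. Each of 19057 genes took the value of its probe with the highest mean level, and 10722 genes were detected on at least 1 array. Of called genes with a further detected probe, that probe had the direction of the call in 10 of 12 in the knockout hearts, 114 of 120 in the knockout culture, 164 of 184 with PDGF-BB at 12 h, 123 of 142 at 24 h, 306 of 311 with the 3 factors, 364 of 395 for the 3 factors against PDGF-BB and 246 of 295 between the untreated cultures. The median detected probe lay 5.12 to 6.14 times above background on each array. Summaries used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for figures.

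Groups followed the labels, with 1 array each, so the comparisons of 2 arrays have no test. The only tests are those of limma with both untreated cultures as a group of 2, on 1 residual degree of freedom. A gene was measured where its detection p was under 0.01 on at least 1 of the 2 arrays compared, and called where it also differed by at least 1 on the log2 scale and was detected on the brighter array. For a gene with no probe detected on the dimmer array, the fold bound is the ratio of the brighter level to the lowest level of a detected probe on the dimmer array, or to the gene's own level where that was higher. Comparisons were knockout with control hearts, knockout with control culture, PDGF-BB at 12 h and at 24 h and the 3 factors with the vehicle culture, the 3 factors with PDGF-BB at 24 h, and the vehicle culture with the control culture. Each culture comparison was repeated with the other untreated culture. Overlaps of called genes were set beside the number that independence gives, and the shared vehicle array was modelled by 100 simulations of groups without response.

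Gene lists, 14 of pathways and 10 of cell types, were each summarized by the median difference of the measured members, where at least 3 were measured, and by its percentile among 10000 random lists of the same size matched on mean level in 20 bins. Among the lowest or highest 2.5% of these fell 83 of 159 medians over the 7 comparisons, where 7.95 would by chance if genes were independent. The untreated vehicle culture against the control culture alone gave 13 of 23. The knockout culture gave 15 of 23, PDGF-BB against vehicle 12 of 22 at 12 h and 8 of 23 at 24 h, and the 3 factors 17 of 23. In cultures, a percentile outside the limits therefore does not by itself mark a response to knockout or ligand. Lists share members: 8 of 17 fibroblast genes and 9 of 36 matrix genes with a probe belong to another list too. The neural list had too few measured members for a median. Named genes are Pdgfra and Pdgfrb; up to 12 called genes with the largest difference per direction, RIKEN, clone and predicted genes left out, which in culture comparisons with an untreated culture had to differ by at least 1 from the other untreated culture as well; up to 4 members, in the direction of its median, of each list outside the percentiles and up to 2 of others; and a panel of EMT and epicardial genes. A panel gene with no named probe is not analysed here, and 1 gene that the rule names in the knockout hearts is not reported here.

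The method was tested on simulated data with planted differences. All 50 genes planted at a difference of 2 were recovered in each direction, and 64% to 82% of those planted at 1.2. Of 7423 unchanged genes, 1 was called at the spread between the 2 hearts and 48 at that between the knockout and control culture. At the spread between the 2 untreated cultures, used for PDGF-BB at 12 h against vehicle, 378 were called. No spread came from replicates, and the first 2 came from the compared arrays themselves, so these are not rates of false calls. Alternatives tried were no background correction, median centring in place of quantile normalization, hearts and cultures normalized apart, the authors' processed values, an offset of 50, detection on both arrays, no detection filter, the mean of all probes of a gene, the other untreated culture, the mean of both untreated cultures, limma with both untreated cultures as a group of 2, and leaving out genes brighter in the heart. The authors' values were used only within a set.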

Results

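RNA was measured on 8 Illumina mouse bead arrays, from hearts and epicardial cultures of E12.5 mouse embryos. The epicardium is the outer cell layer of the heart, from which mesenchymal cells arise by epithelial to mesenchymal transition (EMT). The arrays covered 2 whole-heart samples, control and epicardium-specific knockout of the PDGF receptor genes Pdgfra and Pdgfrb, and 6 epicardial cultures. The cultures were a control culture, a receptor knockout culture and a wild type culture given vehicle for 2 days. Wild type cultures were also given 20 ng/ml PDGF-BB (a ligand of both receptors) for 12 h or 24 h. Another wild type culture was given 20 ng/ml PDGF-BB, 10 ng/ml TGF-β1 and 25 ng/ml bFGF for 2 days (the 3-factor culture). Each array held 1 pool of at least 3 hearts or cultures, so no group had a replicate. P-values were computed only with limma, with the 2 untreated wild type cultures taken as a group of 2, which leaves 1 residual degree of freedom. Between 14557 and 16661 probes per array had a detection p under 0.01 (32.15% to 36.79% of the probes).

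A gene was called where its log2 level differed by at least 1 between 2 arrays and it was detected on the brighter one. "Rose" and "fell" are used only of such genes, and all differences are on the log2 scale unless a fold is named. Where a gene was not detected on the dimmer array, the smallest fold that the detection limit allows is given instead. A gene's value is that of its probe with the highest mean level, and where another detected probe of a called gene named below differed by under 0.5 in that direction, its difference is given. Each gene list was fixed before the data were examined, and the percentile beside its median is its place among 10000 random lists matched on size and expression, which describes these arrays and is not a test across animals.

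The deleted genes came first as a check of the labels. Pdgfra (Entrez gene 18595) had a level of 7.43 in the control hearts and 5.80 in the knockout hearts. Its level was 11.61 in the control culture, 10.49 in the knockout culture and 10.21 in the wild type vehicle culture, so the knockout culture lay below one untreated culture and above the other. With PDGF-BB it was 11.08 at 12 h and 10.95 at 24 h, and in the 3-factor culture it was 8.47. Pdgfrb (Entrez gene 18596) was dim everywhere, with 5.62 in the control hearts, a level without detection in the knockout hearts, 6.12 in the control culture, 5.85 in the knockout culture, 6.18 in the vehicle culture, 6.44 and 6.13 with PDGF-BB at 12 h and 24 h, and 6.99 in the 3-factor culture. Where the probes lie relative to the deleted part of either gene is not known here, so these levels check the labels only in part.

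**Figure D1:**
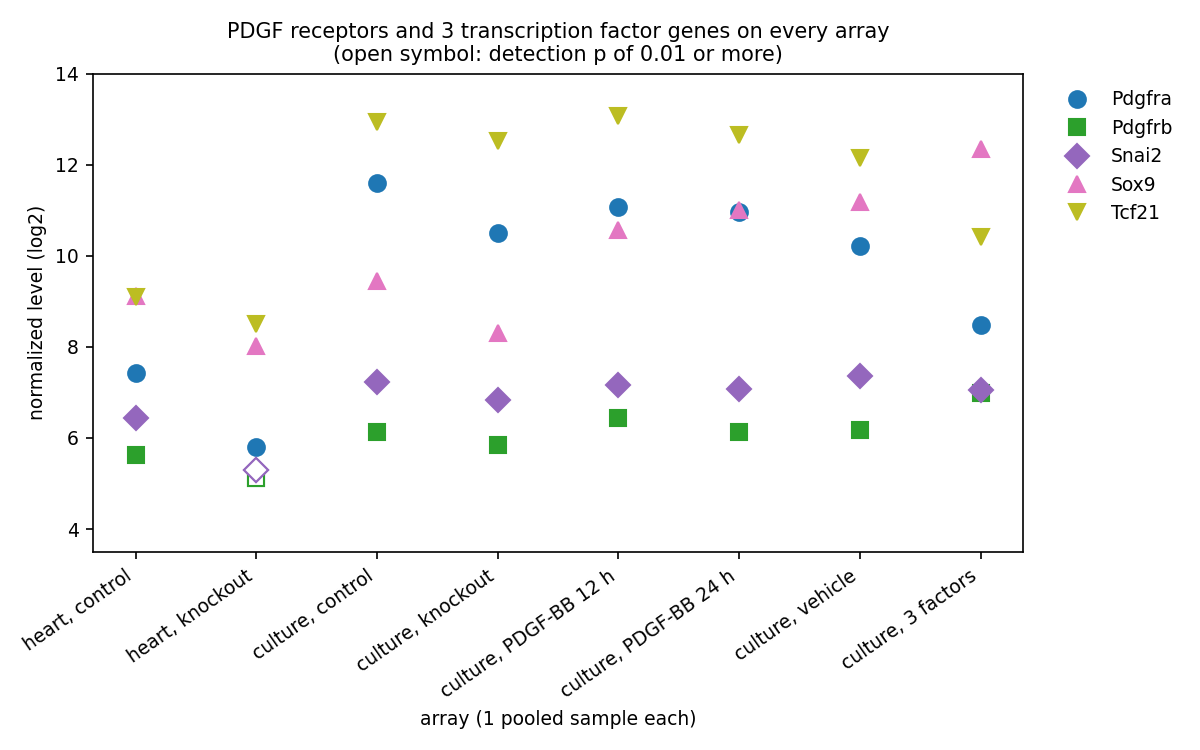
Normalized log2 levels (vertical axis) of Pdgfra, Pdgfrb, Snai2, Sox9 and Tcf21 on each of the 8 arrays (horizontal axis), with 1 symbol per pooled sample and open symbols for a detection p of 0.01 or more. Pdgfra and Sox9 lay lower in the knockout hearts than in the control hearts, and Sox9 was highest in the 3-factor culture, at 12.33.

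The comparison of knockout with control hearts asks which transcripts of the whole heart differ with the epicardium-specific knockout. Several mesenchymal genes were lower in the knockout hearts, among them Pdgfra (-1.63), a target of the knockout. Others were the EMT and cartilage transcription factor Sox9 (-1.10), the matrix glycoprotein Mfap4 (-1.11) and the EMT transcription factor Snai2, which fell at least 1.78-fold. Fibroblast, EMT and matrix gene lists had medians below 0, while those of cardiomyocyte, endothelial and smooth muscle genes lay near 0. In all, 59 of 8915 measured genes were called, 18 higher and 41 lower.

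Among EMT factors and mesenchymal genes, 2 of 18 measured genes fell and 0 rose, with a median difference of -0.24 at percentile 0.01. The transcription factors Twist1 and Zeb2 had differences of -0.84 and -0.58, and Zeb1 one of -0.26, none past the rule of size. Among collagen and extracellular matrix genes, 1 of 27 measured genes fell and 0 rose, with a median difference of -0.18 at percentile 0.00. Below the rule lay the proteoglycan Lum (-0.90) and the collagens Col6a1 (-0.90, with -0.40 for another probe) and Col14a1 (-0.74, with -0.19 for another probe). In the fibroblast list, 1 of 12 measured genes fell, Pdgfra, a target of the knockout, and 0 rose. The list had a median difference of -0.26 at percentile 0.03. Its members Fbln2, a matrix protein (0.38 for another probe), and Tcf21, a transcription factor of epicardium and fibroblasts, each differed by -0.60, and Aldh1a2, which makes retinoic acid in the epicardium, by -0.05. Tbx18 and Snai1 were not detected in either heart sample. Cdh1, the epithelial cadherin, was detected in the knockout hearts alone, at a level at least 1.10-fold above the control hearts' limit of detection and short of the rule.

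Lists of other cell types in the heart lay away from 0 as well. For macrophage and leukocyte genes, 0 of 14 measured genes passed the rule of size, with a median difference of -0.25 (-0.19 with undetected members at their bound) at percentile 0.75, with -0.83 for the Fc receptor Fcgr3, -0.46 for Mrc1, -0.41 for Fcer1g and -0.34 for the complement gene C1qc. Interferon response genes showed the same sign, in that 0 of 10 measured genes passed the rule of size, with a median difference of -0.30 (-0.18 with undetected members at their bound) at percentile 0.68, with -0.61 for Ifit2 and -0.57 for Isg15. Erythroid genes lay above 0, in that 0 of 8 measured genes passed the rule of size, with a median difference of 0.29 at percentile 99.97, with 0.71 for the embryonic globin gene Hbb-bh1 and 0.57 for the red cell anion exchanger Slc4a1. Medians of other lists were within the middle of their random lists. They were -0.02 for 24 cardiomyocyte genes, 0.03 for 16 endothelial and endocardial genes and 0.00 for 10 smooth muscle and pericyte genes. The median was 0.02 for 9 epicardial genes, -0.16 for 9 valve mesenchyme genes, -0.01 for 13 epithelial genes, -0.07 for 28 cell cycle genes and -0.01 for 13 reference genes. Stress and unfolded protein response genes had a median of 0.11 at percentile 96.2.

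Outside the lists, large decreases among genes detected on both arrays included those of Tmem68 (-2.38), the replication factor Pclaf (-1.76), the amino acid transporter Slc38a5 (-1.76), Zfp157 (-1.28) and Erdr1 (-1.25). Genes that fell below detection were Xist, the RNA that silences an X chromosome (at least 10.3-fold lower), Angptl7 (at least 2.5-fold), the phosphodiesterase Pde1a (at least 2.5-fold), the fatty acid oxidation gene Hadha (at least 1.82-fold) and Zfp933 (at least 1.72-fold). The Y-linked Eif2s3y was at least 1.81-fold higher in the knockout hearts, so the heart pools may have differed in sex. Ncf4, a subunit of the phagocyte oxidase, rose by 1.69. Increases were also seen in Zfp869, the mitochondrial gene ND5, the calcium-binding Casq1, the kinase subunit Prkar2b and Mtmr12, by 1.21, 1.18, 1.16, 1.14 and 1.12 (0.36 for another Zfp869 probe). Genes detected in the knockout hearts alone were Prap1 (at least 10.1-fold higher), Guca2b (at least 4.08-fold), Chst7 (at least 2.17-fold), myeloperoxidase Mpo (at least 2.24-fold), Smpd3 (at least 1.45-fold) and Rif1 (at least 1.35-fold, but below 0 with median centring). The number of called genes was small and moved with the processing, to 16 without background correction. Of 12 called genes with a further detected probe, that probe had the same sign in 10 and passed 0.5 in 5.

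The knockout culture was set against the control culture to ask which genes differ in epicardial cells labelled as knockout, in which Pdgfra and Pdgfrb were still detected. As lists, epithelial and macrophage genes were higher in the knockout culture, among them the keratin gene Krt14 (2.18) and the Fc receptor subunit Fcer1g (1.78). Lower mesenchymal and contractile genes included Pdgfra (-1.12, but 0.28 against the vehicle culture), Sox9 (-1.15), the TGF-β family gene Tgfb2 (-1.29) and smooth muscle actin Actg2 (-1.33). Cell cycle genes lay below 0 as a list, with no member past the rule. Of 9762 measured genes 407 were called, 184 higher and 223 lower, and 128 and 112 of them also differed by at least 1 in that direction from the wild type vehicle culture, which the authors had normalized in another set of arrays.

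Among epithelial junction and keratin genes, 5 of 14 measured genes rose and 0 fell, with a median difference of 0.50 at percentile 100. Beside Krt14, the junction genes F11r (1.23) and Cldn15 (1.20, with 0.47 and 0.85 for other probes) rose, and Krt19 was at least 2.95-fold higher. Against the vehicle culture the list's median was 0.27 at percentile 89.3 (0.01 with undetected members at their bound), and Krt19 had a difference of -0.70. In the epicardial list, 1 of 12 measured genes rose and 0 fell, with a median difference of 0.34 at percentile 99.8. The mesothelial gene Upk3b had a difference of 0.93, Rspo1 one of 0.72 and Anxa8 one of 0.52, while Tcf21 and Aldh1a2 differed by -0.41 and -0.29. Against the vehicle culture the epicardial median was 0.70 at percentile 99.97.

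For EMT factors and mesenchymal genes, 2 of 22 measured genes fell and 0 rose, with a median difference of -0.39 at percentile 0.00, and against the vehicle culture the median was -0.52 at percentile 0.03 (-0.45 with undetected members at their bound). The forkhead factor Foxc1 fell by 1.01, and below the rule lay tenascin Tnc (-0.75), Prrx1 (-0.68), Zeb1 (-0.60), Snai2 (-0.38), Snai1 (-0.24), Twist1 (-0.09) and, above 0, Zeb2 (0.54). Sox9 had a difference of -2.87 from the vehicle culture. Of the TGF-β targets, 2 of 19 measured genes fell and 0 rose, with a median difference of -0.25 at percentile 0.27, against -0.16 at percentile 16.8 when set against the vehicle culture. The integrin gene Itga11 had the lowest value of these, -1.91 (-0.27 against the vehicle culture), with Ccn2 at -0.93 and Cald1 at -0.67. Among smooth muscle and pericyte genes, 2 of 9 measured genes fell and 0 rose, with a median difference of -0.56 at percentile 0.01. Desmin Des had -1.01, Lmod1 -0.93 and Tagln -0.75, and the median against the vehicle culture was -1.79 at percentile 0.00 (-1.57 with undetected members at their bound). Among cell cycle genes, 0 of 30 measured genes passed the rule of size, with a median difference of -0.43 at percentile 0.00. The mitotic genes Aurka, Cenpa, Prc1 and Nusap1 had differences of -0.92, -0.81, -0.73 and -0.70 (0.02 for another Cenpa probe), and against the vehicle culture the median was -0.75 at percentile 0.00.

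Macrophage and leukocyte markers lay above 0 together, in that 4 of 16 measured genes rose and 0 fell, with a median difference of 0.82 at percentile 100, led by Fcer1g and the complement genes C1qb (1.37), C1qa (1.13) and C1qc (1.11). Against the vehicle culture all 15 measured members rose, with a median of 1.78. Interferon response genes lay above 0, in that 1 of 15 measured genes rose and 1 fell, with a median difference of 0.26 at percentile 97.6. Ifit3 had 1.47, Rsad2 0.99, Ifi35 0.97 and Ifi27 0.74. Against the vehicle culture the interferon median was 0.91 at percentile 99.95. Cytokine and chemokine genes went the other way, in that 1 of 14 measured genes rose and 2 fell, with a median difference of -0.50 at percentile 0.00. Inhba, which encodes an activin subunit, fell by 2.26 and Saa3 by 1.19, though Saa3 had 5.16 against the vehicle culture, while Ccl2 and Ccl7 had differences of -0.99 and -0.95. This list's median turned to 0.31 (0.25 with undetected members at their bound) against the vehicle culture, as did those of the immediate-early response (0.24 at percentile 99.4, then -0.22) and of the stress and unfolded protein response (0.18 at percentile 98.8, then -0.14). In these the transcription factors Atf3 (1.09) and Ddit3 (1.23, and 0.31 against the vehicle culture) rose. Endothelial genes, none past the rule, had a median of 0.34 at percentile 98.3, with 0.70 for Icam2 and 0.55 for Flt1. Their median was 0.29 at percentile 84.2 against the vehicle culture and -0.004 without a detection filter.

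Transcripts of heart muscle, blood and the sex chromosomes differed too. Among cardiomyocyte genes, 7 of 17 measured genes fell and 0 rose, with a median difference of -0.72 (-0.49 with undetected members at their bound) at percentile 0.00, with -2.55 for the myosin light chain Myl2, and Nppa, Actc1 and Myl3 at least 7.84-fold, at least 4.32-fold and at least 4.30-fold lower. Erythroid genes followed, in that 3 of 4 measured genes fell and 0 rose, with a median difference of -2.19 (-1.73 with undetected members at their bound) at percentile 0.00, with the globin genes Hba-a1 and Hbb-y at least 13.2-fold and at least 8.62-fold lower. The sex-linked list had a median of -0.95 at percentile 0.08 (-0.34 with undetected members at their bound), in which Xist rose by 1.56, and the Y-linked Eif2s3y and Kdm5d were at least 6.48-fold and at least 1.59-fold lower. Lists within the middle of their random lists were collagen and extracellular matrix (-0.03), ERK feedback targets (-0.02), fibroblast (0.04), valve mesenchyme (-0.15), glycolysis and hypoxia (0.05), cholesterol synthesis (0.07), retinoic acid metabolism and response (0.28) and reference genes (0.02). Of these, ERK feedback targets had -0.49 at percentile 0.65 against the vehicle culture, and glycolysis and hypoxia genes 0.39 at percentile 99.5.

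The largest increases that held against both untreated cultures were in the protease inhibitor genes Cst9 (2.98) and Cstdc4 (2.11), the annexin Anxa4 (2.94, but 0.28 for another probe), the glycosyltransferase B4galnt2 (2.67), the leukocyte gene S100a8 (2.48), Vat1l (2.35), Pkhd1l1 (2.31), the myosin Myo5b (2.26) and the clotting factor subunit F13a1 (2.19). The creatine kinase Ckmt1 was at least 9.78-fold higher and the transporter Abca4 at least 4.14-fold. The kinase subunit Prkar2b fell by 2.57, and Tm7sf3, Plac8, Pou6f1, Unc13c, Kcne1l and Hbb-bs were at least 7.94-fold, at least 9.45-fold, at least 5.60-fold, at least 3.82-fold, at least 4.02-fold and at least 4.16-fold lower. With the vehicle culture in place of the control culture 1426 genes were called, and Pdgfra then had a difference of 0.28. With both untreated cultures taken as a group of 2, limma called 0 of 10250 genes at an adjusted p under 0.05, and 386 had an unadjusted p under 0.05.

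The receptor knockout shared little between hearts and cultures. Across 8262 genes measured in both, the differences had Pearson r 0.026 and Spearman correlation 0.045, computed across genes, which are not independent replicates. Lower in both were 6 genes, where independence would give 0.71: Pdgfra, Sox9, Mfap4, Slc38a5, Unc13c and Zfp160. Pdgfra is a target of the knockout in both, so the value under independence does not apply to it. Higher in both were 2 genes, where independence would give 0.12: ND5 and Smpd3. Called in opposite directions were 3 genes, Eif2s3y, Prkar2b and Xist, where independence would give 0.64. Xist and the Y-linked Eif2s3y would differ between pools with a different mix of sexes, so the value under independence does not apply to them. With the vehicle culture as the culture control, 7 genes changed in the same direction and 8 in opposite ones, and Pdgfra was no longer among the former. Those of these genes outside the rule for named genes were chosen after their values were seen.

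The vehicle culture and the control culture are both labelled wild type and vehicle, so their difference measures how far 2 untreated cultures lay apart. As lists, globin and smooth muscle genes were higher in the vehicle culture, and macrophage, heart muscle and matrix genes were lower. Of 9757 measured genes 1031 were called, 326 higher and 705 lower. The knockout culture had 407 called genes against the control culture and 1426 against the vehicle culture, and the PDGF-BB cultures had 659 and 553 against vehicle. The authors had normalized the vehicle culture with the hearts and the 3-factor culture, and the control culture with the knockout and PDGF-BB cultures, so set and culture cannot be told apart here.

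The globin genes Hbb-bt, Hbb-y, Hba-a1, Hba-x and Hbb-bs rose by 4.43, 4.11, 4.03, 3.96 and 3.63, and Hbb-bh1 was at least 3.56-fold higher. In the erythroid list, 4 of 5 measured genes rose and 0 fell, with a median difference of 3.96 at percentile 100. Among smooth muscle and pericyte genes, 6 of 11 measured genes rose and 1 fell, with a median difference of 1.01 at percentile 100, with desmin at 1.92, the proteoglycan Cspg4 at 1.45, and smooth muscle myosin Myh11 and its activator Myocd at least 3.15-fold and at least 3.51-fold higher. The cornified envelope gene Sprr2k (3.35), the potassium channel subunit Kcne1l (3.04), the noncoding RNA Rian (2.51), the natriuretic peptide Nppb (2.5), the transcription factors Sox11 (2.34), Sox9 (1.72) and Snai1 (1.34) rose, and Krt19 was at least 4.79-fold higher. The acute phase gene Saa3 (-6.35), Angptl7 (-5.13), Serpina3n (-4.01), Cd200 (-3.87, with -1.50 and -0.30 for other probes), the myosin Myh8 (-3.19, with -0.89 and -0.39 for other probes) and Pdgfra (-1.39) were lower. Fpr2, Vsig4, Mmp12, Sirpb1a, Slco4a1, Npy and Ephb1 were at least 13.2-fold, at least 9.85-fold, at least 8.94-fold, at least 9.27-fold, at least 6.74-fold, at least 6.78-fold and at least 5.12-fold lower.

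Among macrophage and leukocyte genes, 6 of 16 measured genes fell and 0 rose, with a median difference of -0.90 at percentile 0.00, with -3.05 for Adgre1, -2.48 for Lyz2, -2.01 for Cd14 and -2.0 for Csf1r, the receptor of a macrophage growth factor, another probe of which had -0.47. Among cardiomyocyte genes, 2 of 17 measured genes rose and 7 fell, with a median difference of -0.81 (-0.19 with undetected members at their bound) at percentile 0.04, with Nppa at -2.30, Actc1 at -1.69 and Actn2 at least 2.59-fold lower. Medians below 0 outside the middle of the random lists were also those of the epicardial (-0.65), fibroblast (-0.38 (-0.31 with undetected members at their bound)), glycolysis and hypoxia (-0.36 (-0.28 with undetected members at their bound)), collagen and extracellular matrix (-0.20) and interferon response (-0.48 (-0.24 with undetected members at their bound)) lists. Among their members were Msln at -1.46, Lum at -1.72, Aldoc at -2.25, elastin Eln at -2.27 and Gbp2 at -2.23. Of 4 measured sex-linked genes 2 fell, the Y-linked Eif2s3y (-2.16) and Kdm5d (at least 1.43-fold lower), with a median of -0.82 at percentile 2.57 (-0.55 with undetected members at their bound). Cytokine and chemokine genes, 2 higher and 5 lower of 14, had a median of -0.36 at percentile 2.86 (0.12 with undetected members at their bound). Medians above 0 were those of the immediate-early response (0.44), ERK feedback target (0.35), cell cycle (0.28) and stress (0.28) lists, which held Egr3 at 1.52, Lif at 1.32, the ribonucleotide reductase subunit Rrm2 at 1.35 and Ddit3 at 0.92. Tcf21, Twist1, Zeb1, Zeb2, Snai2, Aldh1a2 and Pdgfrb differed by -0.78, 0.35, 0.15, -0.21, 0.14, 0.43 and 0.06.

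The PDGF-BB cultures ask which epicardial genes respond to the ligand after 12 h and 24 h. The vehicle culture was exposed for 2 days, so exposure times differ in both comparisons with it. At 12 h the heart muscle genes Nppa, Actc1 and Myl4 and the interferon response gene Ifit3 were higher than in both untreated cultures. The differences were 5.27, 2.78, 2.27 and 1.29 against vehicle and 2.96, 1.08, 1.89 and 1.24 against the control culture. Nppa varied without ligand too, with levels of 8.2 in the control and 5.9 in the vehicle culture. It was 11.2 at 12 h and 6.0 at 24 h. Heart tissue left in the 12 h culture was not tested as a cause. Against the control culture, which is in the same normalization set, Sox9 rose by 1.12 and the pericyte gene Cspg4 by 1.23. The cell cycle and ERK feedback lists lay above 0 there. The untreated vehicle culture lay above the control culture in Sox9, Cspg4 and both lists too. Against vehicle 659 of 9605 measured genes were called, 432 higher and 227 lower. Against the control culture 54 of 9686 were called, 24 higher and 30 lower. Only 13 higher genes and 1 lower gene met the rule against both.

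Other genes higher against both were the calcium pump regulator Sln (at least 3.48-fold and at least 4.13-fold), the muscle gene Mybphl (at least 1.32-fold and at least 1.56-fold) and the cornified envelope gene Sprr1a (at least 1.72-fold and at least 2.04-fold). The receptor Tnfrsf18, the muscle gene Csrp3, the antiviral Rsad2 and the peptide hormone Cck were at least 3.08-fold, at least 2.62-fold, at least 2.98-fold and at least 2.51-fold higher than in vehicle and rose by 1.23, 1.40, 1.44 and 1.05 against the control culture, where another Csrp3 probe had 0.30. The chemokine Cxcl10 was at least 1.89-fold higher than in vehicle. Olfml1 fell in both comparisons, with -1.04 and -1.26. Pdgfra lay between the untreated cultures, with differences of 0.86 and -0.53, as did Sox9, with -0.60 and 1.12. Snai1 had -0.96 and 0.39, Snai2 -0.20 and -0.06 and Twist1 -0.17 and 0.18. Zeb1 had -0.32 and -0.16, Zeb2 0.13 and -0.07, Tcf21 0.92 and 0.14, and Aldh1a2 -0.33 and 0.10.

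Within the set, against the control culture, ERK feedback targets had a median of 0.22 at percentile 99.9, with 0.74 for Lif, 0.55 for the ERK phosphatase Dusp5 and 0.53 for Plaur. Against vehicle it was 0.05 at percentile 68.7 (-0.07 with undetected members at their bound). The cell cycle list had 0.23 at percentile 100 against the control culture, with 0.72 for the cyclin Ccne2 and 0.69 for Rrm2, and 0.03 at percentile 79.1 against vehicle. Of cardiomyocyte genes, 5 of 17 rose and 2 fell against the control culture, and 6 of 16 rose and 1 fell against vehicle. The former 2 were Myl2 and Myl3, named after their values were seen. The medians were 0.39 at percentile 100 and 0.66 at percentile 99.98 (0.42 with undetected members at their bound), but -0.018 against vehicle with detection required on both arrays. Interferon response genes had 0.08 at percentile 85.1 and 0.88 at percentile 99.99 (0.51 with undetected members at their bound). In cytokine and chemokine genes the medians were 0.15 at percentile 98.1 and 0.54 at percentile 99.97 (0.22 with undetected members at their bound), and Saa3 had -0.32 and 6.03.

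Several lists turned sign between the untreated cultures. Among macrophage and leukocyte genes against vehicle, 6 of 15 measured genes rose and 0 fell, with a median difference of 0.83 at percentile 100, led by Lyz2 (2.26), Cd14 (2.10), Adgre1 (1.92) and Csf1r (1.60). Set against the control culture, the median was -0.13 at percentile 1.68, and Lyz2, Adgre1 and Csf1r had -0.22, -1.13 and -0.40 (0.32 for another Csf1r probe). Smooth muscle and pericyte genes had medians of -0.40 at percentile 0.21 and 0.30 at percentile 100 (0.21 with undetected members at their bound), and epicardial genes 0.32 at percentile 99.1 and -0.27 at percentile 0.02. Fibroblast genes had 0.37 at percentile 99.9 and -0.13 at percentile 1.74, collagen and extracellular matrix genes 0.25 at percentile 99.9 (0.13 with undetected members at their bound) and -0.03 at percentile 24.1. Immediate-early genes had -0.35 at percentile 0.12 and 0.11 at percentile 96.7. Below 0 in both were epithelial genes, at -0.48 at percentile 0.05 and -0.11 at percentile 11.7, with Krt19 at -2.03 against vehicle and not detected in the control culture, and erythroid genes, at -4.06 and -0.09, with Hba-a1 at -4.22 and -0.19. Glycolysis and hypoxia genes had 0.45 at percentile 100 and 0.03 at percentile 76.4. In limma with both untreated cultures as a group of 2, 0 genes were called and 25 had an unadjusted p under 0.05.

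At 24 h of PDGF-BB the intermediate filament gene Nes was higher than in both untreated cultures, by 1.02 against vehicle and 1.22 against the control culture (0.12 and 1.23 for another probe), and the endothelial receptor Tek was lower, with -2.03 and -1.05. Within the normalization set, against the control culture, Sox9 rose by 1.55, the ERK targets Lif and Dusp5 by 1.38 and 1.14, and the immediate-early factor Egr3 by 1.86. Cell cycle and ERK feedback lists lay further above 0 than at 12 h. Sox9, Lif and Egr3 also rose in the untreated vehicle culture against the control culture. Its cell cycle list lay at 0.28 and its ERK feedback list at 0.35 there, so these rises cannot be credited to the ligand alone. Against vehicle 553 of 9522 measured genes were called, 362 higher and 191 lower. Against the control culture 119 of 9698 were called, 40 higher and 79 lower. Only 2 higher and 5 lower genes met the rule against both.

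The other higher gene was Nrn1, at least 3.71-fold above vehicle and 1.0 above the control culture. The other lower genes with a full name were the sugar kinase Fggy (-1.54 and -1.47), Olfml1 (at least 2.15-fold and at least 2.49-fold lower) and Xist (at least 3.53-fold and at least 5.32-fold lower). Xist was detected in both untreated pools but not in the 24 h pool, where the Y-linked Eif2s3y had a level of 7.82. For Xist a different mix of sexes in the pools cannot be told apart from a response to the ligand. Pdgfra had differences of 0.74 and -0.65, Pdgfrb -0.06 and 0.0, Snai1 -0.85 and 0.50, Snai2 -0.28 and -0.15 and Twist1 -0.17 and 0.18. Zeb1 had -0.37 and -0.21, Zeb2 0.03 and -0.18, Tcf21 0.51 and -0.27, and Aldh1a2 -0.48 and -0.05. Sox9 had -0.18 against vehicle.

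ERK feedback targets had a median of 0.63 at percentile 100 against the control culture and of 0.24 at percentile 97.8 (0.14 with undetected members at their bound) against vehicle. Dusp4 was at 0.67 and 1.20, with 0.00 and -0.40 against vehicle for 2 other probes, and Etv4 at 0.87 and 0.63. Cell cycle genes had 0.41 at percentile 100 and 0.06 at percentile 87.2, with Birc5 at 0.83 and Foxm1 at 0.67 against the control culture. Immediate-early genes had 0.27 at percentile 99.99 and -0.11 at percentile 22.4. Turned in sign were smooth muscle and pericyte genes, with 0.40 at percentile 99.99 (0.28 with undetected members at their bound) against the control culture and -0.30 at percentile 1.70 against vehicle, and macrophage and leukocyte genes, with -0.30 at percentile 0.02 and 0.63 at percentile 100. So were epicardial genes, with -0.23 at percentile 2.06 and 0.41 at percentile 99.7 (0.23 with undetected members at their bound), and erythroid genes, with 1.81 and -2.15. Fibroblast genes had 0.02 at percentile 63.0 and 0.23 at percentile 98.8 (0.14 with undetected members at their bound), and cytokine and chemokine genes 0.12 at percentile 91.8 and 0.89 at percentile 100 (0.31 with undetected members at their bound). Glycolysis and hypoxia genes had 0.04 at percentile 78.5 and 0.34 at percentile 99.9, and cardiomyocyte genes -0.37 at percentile 0.04 (-0.28 with undetected members at their bound) and 0.20 at percentile 90.6 (0.02 with undetected members at their bound). In limma with the untreated pair, 0 genes were called and 19 had an unadjusted p under 0.05.

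The PDGF-BB cultures at 12 h and 24 h were close to each other. Against vehicle, 413 called genes were shared in direction, 282 higher and 131 lower, and 1 gene, Xist, was opposite. The differences had Pearson r 0.909 and covariance 0.268 across 9354 genes. Both comparisons use the same vehicle array, and simulated groups without any response that shared it gave 287.8 shared genes, r 0.501 and covariance 0.206 on average over 100 runs. Against the control culture 22 genes were shared, where 0.4 were shared in simulated groups without response. The simulated groups called 1028.5 genes against vehicle, where the 12 h culture had 659, and 9.2 against the control culture, where it had 54, so neither simulated count of shared genes is at the observed number of calls. Of the 22 genes, Col7a1, Cspg4, Nppb, Sh2d5, Sox9 and Sprr2k were higher. The other 16 were lower, among them Lum, Sfrp2 and Fgf8, and all were named here after their values were seen. Cspg4, Nppb, Sox9 and Sprr2k also rose in the untreated vehicle culture against the control culture. With a separate untreated culture for each time, r was -0.187 or -0.379.

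**Figure D2:**
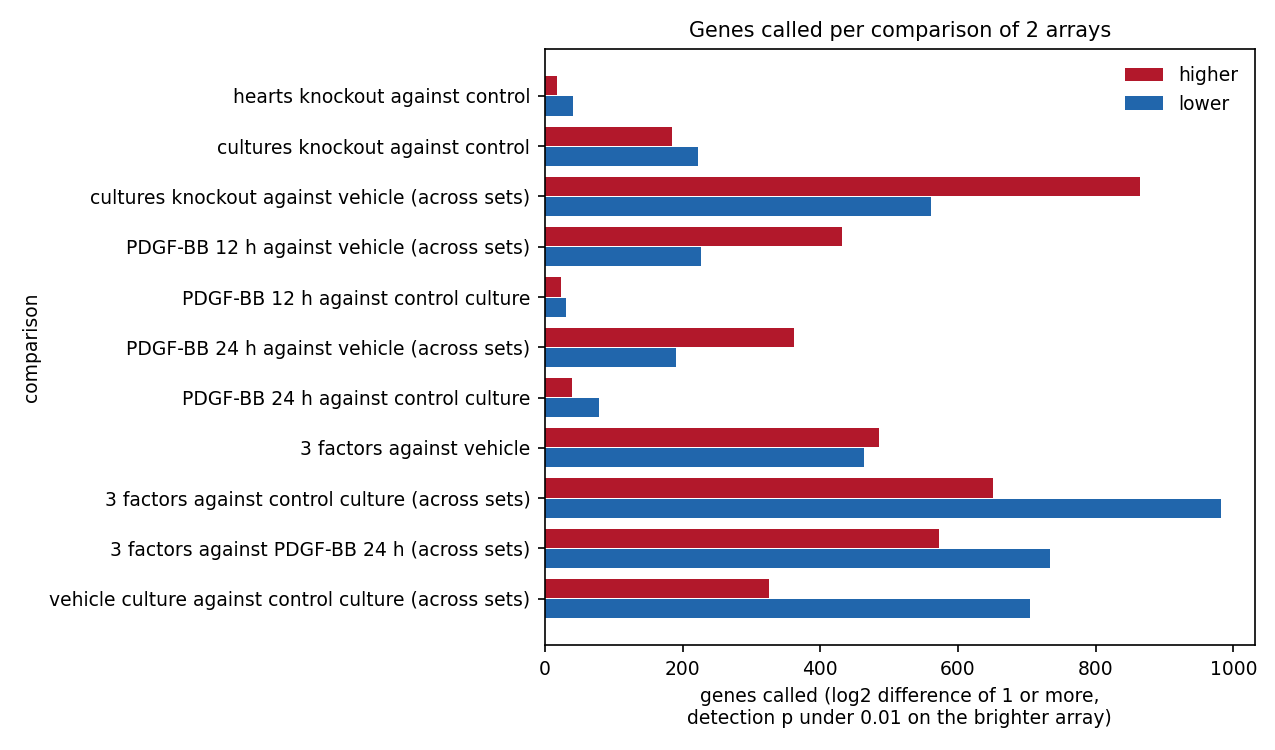
Number of genes called higher (red) and lower (blue) (horizontal axis) in each comparison of 2 arrays (vertical axis), with comparisons between the authors' normalization sets marked as across sets. PDGF-BB at 12 h called 659 genes against vehicle and 54 against the control culture, and the untreated cultures differed in 1031.

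The culture with PDGF-BB, TGF-β1 and bFGF was set against the vehicle culture to ask which genes respond to the combined factors over 2 days. Both arrays are in the same normalization set. Sox9 (1.16), the TGF-β targets Itga11 (3.07) and Pmepa1 (2.02), and the valve matrix genes Has2 (2.37) and Vcan (1.75) rose. Of fibroblast and epicardial genes 7 of 12 and 8 of 13 fell, among them the proteoglycan Dcn (-3.53), Thy1 (-2.27), Tcf21 (-1.75), Pdgfra (-1.74) and the mesothelial gene Upk3b (-2.21). Cell cycle genes were lower as a list. As lists, cytokine, interferon and macrophage genes were higher, and of these 3 lists only the cytokine list lay outside its random lists against the control culture too. Of 9183 measured genes 950 were called, 486 higher and 464 lower, and 246 and 295 of them met the rule against the control culture too.

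Among TGF-β targets, 4 of 21 measured genes rose and 2 fell, with a median difference of 0.49 at percentile 99.98, with Tgfbi at 1.45 (0.01 against the control culture) and the oxidase Nox4 at least 5.92-fold higher. Among valve mesenchyme genes, 4 of 8 measured genes rose and 1 fell, with a median difference of 1.04 at percentile 100, with the tendon factor Scx at 1.41. For EMT factors and mesenchymal genes, 2 of 22 measured genes rose and 2 fell, with a median difference of 0.22 at percentile 98.5. The fibronectin receptor subunit Itga5 rose by 1.16, Itgb1 and Sox4 had 0.97 and 0.95, and Snai1, Snai2, Twist1, Zeb1 and Zeb2 had -0.11, -0.31, -0.25, -0.38 and 0.17. Against the control culture Snai1 and Sox9 had 1.23 and 2.88. ERK feedback targets had a median of 0.32 at percentile 99.1, with 0.89 for Dusp5 and 0.78 for Lif, and 1 of 12 fell.

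In the fibroblast list, 1 of 12 measured genes rose and 7 fell, with a median difference of -1.74 at percentile 0.00. Lum was at least 10.3-fold lower and collagen Col3a1 had -2.67. In the epicardial list, 1 of 13 measured genes rose and 8 fell, with a median difference of -1.46 (-1.36 with undetected members at their bound) at percentile 0.00, with Bnc1 at -2.01 and Gpm6a and Lrrn4 at least 2.35-fold and at least 2.96-fold lower, while Aldh1a2 had 0.07. Among collagen and extracellular matrix genes, 4 of 29 measured genes rose and 7 fell, with a median difference of -0.26 (-0.19 with undetected members at their bound) at percentile 0.08, with Ogn at -3.22 and elastin Eln at least 4.21-fold lower. Among smooth muscle and pericyte genes, 4 of 12 measured genes fell and 0 rose, with a median difference of -0.41 at percentile 0.20, with Mylk at -3.21, desmin at -1.38, Actg2 at -1.31 and Myh11 at -1.01. Set against the control culture, this median turned to 0.55, with desmin at 0.54. Among cell cycle genes, 7 of 29 measured genes fell and 0 rose, with a median difference of -0.81 at percentile 0.00, with the mitotic genes Cdc20 (-1.44), Birc5 (-1.34) and Prc1 (-1.18), which had -0.77, -0.87 and -0.74 against the control culture, and Tpx2 at least 1.80-fold lower. Cholesterol synthesis genes followed, in that 1 of 15 measured genes fell and 0 rose, with a median difference of -0.37 at percentile 0.30, with Stard4 at -1.50.

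Among interferon response genes, 7 of 15 measured genes rose and 0 fell, with a median difference of 1.0 (0.84 with undetected members at their bound) at percentile 100, with Ifit3 at 2.46 and Usp18, Cxcl10 and Rsad2 at least 6.45-fold, at least 3.23-fold and at least 2.93-fold higher. Against the control culture the interferon list had 5 higher and 2 lower genes of 15 and a median of 0.04 at percentile 49.5. For cytokines and chemokines, 6 of 12 measured genes rose and 0 fell, with a median difference of 0.96 at percentile 100, against 0.89 at percentile 100 with the control culture, with the growth factor Hbegf at 2.46, Il11 at 2.29, Cxcl16 at 1.78 and Cxcl2 at least 2.30-fold higher. Among macrophage and leukocyte genes set against vehicle, 7 of 15 measured genes rose and 0 fell, with a median difference of 0.98 at percentile 100, with Aif1 at 2.46, Lyz2 at 1.94, C1qa at 1.51 and Adgre1 at 1.21. The macrophage median against the control culture was -0.03 at percentile 30.7 (0.08 with undetected members at their bound). Lyz2 was at -0.55 there and Adgre1 at -1.84, with 0.32 and -0.51 for other Adgre1 probes. Erythroid genes were lower, in that 4 of 4 measured genes fell and 0 rose, with a median difference of -6.43 (-5.45 with undetected members at their bound) at percentile 0.00, with Hba-a1 at least 174-fold and Hbb-y at least 120-fold lower than in vehicle. Endothelial genes had a median of -0.62 at percentile 0.58 (-0.26 with undetected members at their bound), with Ramp2 at least 1.84-fold lower, of 0.01 against the control culture and of 0.18 with detection required on both arrays. Glycolysis and hypoxia genes had 0.24 at percentile 99.0 and stress genes -0.21 at percentile 1.30, with Pfkl at 1.09 (0.00 for another probe) and Hspa1a at -1.56 (0.27 for another probe), and both medians turned against the control culture, to -0.12 and 0.07. Epithelial, immediate-early, retinoic acid, cardiomyocyte and reference genes had -0.10, -0.06, 0.05, -0.09 and 0.09. Against the control culture the first 2 had 0.42 at percentile 98.8 and 0.44 at percentile 99.6. Against vehicle, members moved both ways: 7 of 15 cardiomyocyte genes rose and 4 fell, and 2 of 16 epithelial genes rose and 4 fell. Of 8 retinoic acid genes 2 rose and 3 fell, and of 18 immediate-early genes 2 rose and 2 fell. Of 13 reference genes 0 were called.

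The largest increases were in Tnfrsf11b, a decoy receptor of bone turnover (4.37), skeletal actin Acta1 (3.36), the chemokine Cx3cl1 (3.29) and the B cell gene Cd72 (3.22). Not detected in vehicle were Srpx2 (at least 11.7-fold), the G protein regulator Rgs4 (at least 9.31-fold), Fermt1 (at least 8.11-fold), the serotonin receptor Htr2b (at least 7.52-fold), the interleukin Il1b (at least 6.44-fold), Akr1c19 (at least 4.94-fold) and Scimp (at least 4.63-fold higher). With undetected levels taken at face value, the decreases ranked largest outside globin genes were those of the growth factor Ptn (at least 31.9-fold), Cyp2s1 (at least 17.1-fold), Fam180a (at least 15.2-fold), the hormone Stc1 (at least 11.4-fold) and Lgi2 (at least 5.60-fold lower). By these bounds the order differs, since Dcn and Lum, named above, fell by more than the bound for Lgi2. With the control culture 1633 genes were called, beside the 950 with vehicle. In limma with the untreated pair 0 genes were called, with 749 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0987.

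The 3-factor culture was also set against the culture given PDGF-BB alone for 24 h, which bears on what TGF-β1 and bFGF add, although the exposure times differ (2 days and 24 h) and the arrays are in different normalization sets. As lists, TGF-β targets and valve mesenchyme genes were higher and fibroblast, epicardial and cell cycle genes lower, as against vehicle. Nox4 was at least 6.48-fold higher, Itga11 rose by 1.91, Has2 by 2.72 and Sox9 by 1.34, while Pdgfra, Tcf21 and Dcn had -2.48, -2.26 and -3.67. Of 9507 measured genes 1307 were called, 573 higher and 734 lower.

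Among TGF-β targets, 6 of 21 measured genes rose and 1 fell, with a median difference of 0.72 (0.50 with undetected members at their bound) at percentile 100, with Pmepa1 at 1.50 and Skil at 1.13 (-0.53 for another probe). Among valve mesenchyme genes here, 5 of 8 measured genes rose and 1 fell, with a median difference of 1.22 at percentile 100, with Vcan at 2.52 and Scx at 1.64. For EMT factors and mesenchymal genes, 6 of 22 measured genes rose and 2 fell, with a median difference of 0.30 at percentile 97.9, with Sox11 at 2.21, Itgb1 at 2.05, Itga5 at 1.89 and Sox4 at 1.39. Snai1, Snai2, Twist1, Zeb1 and Zeb2 had 0.73, -0.02, -0.08, -0.01 and 0.15. In the fibroblast list, 7 of 13 measured genes fell and 0 rose, with a median difference of -2.08 at percentile 0.00, and in the epicardial list, 1 of 13 measured genes rose and 7 fell, with a median difference of -1.57 at percentile 0.00, with Thy1 at -2.52, Upk3b at -2.54 and Upk1b at -2.27. Among cell cycle genes, 12 of 29 measured genes fell and 0 rose, with a median difference of -0.91 at percentile 0.00, with Birc5 at -1.69, Aurkb at -1.55 and Top2a at -1.54. For cholesterol synthesis genes, 2 of 16 measured genes fell and 0 rose, with a median difference of -0.42 at percentile 0.50, with Stard4 at -1.68 and Nsdhl at -1.02. Interferon response genes had a median of 0.62 at percentile 99.7, with Isg15 at 1.97. Of 13 cytokines and chemokines 5 rose and 4 fell, with a median of 0.72 at percentile 99.99 and a mean of 0.13, with Il11 at 1.98 and Inhba at 1.95. Glycolysis and hypoxia genes had -0.23 at percentile 1.65, with Eno1b at -1.17, but a median of 0.10 with detection required on both arrays, and erythroid genes -4.23 (-3.25 with undetected members at their bound). The retinoic acid list had a median of 0.55 at percentile 98.0 and a mean of -0.23, and its median was -0.10 without a detection filter. Smooth muscle and macrophage genes had 0.06 at percentile 58.9 and 0.25 at percentile 94.1.

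Of the genes with the largest differences, Tnfrsf11b (3.75), Acta1 (3.54), Cx3cl1 (3.35) and Ccl17 (3.12) rose, and Srpx2, Rgs4, Fermt1, Megf10, Usp18 and Cyp4f18 were at least 12.8-fold, at least 10.2-fold, at least 8.87-fold, at least 8.05-fold, at least 7.06-fold and at least 7.01-fold higher. The matrix inhibitor of calcification Mgp (-4.74), myosin kinase Mylk (-4.25) and Smpd3 (-3.93) fell, and Angptl7, Hba-a1, Stc1, Ecrg4 and Depp1 were at least 40.1-fold, at least 39.0-fold, at least 38.6-fold, at least 10.9-fold and at least 7.69-fold lower. Each number of called genes across sets stands beside the 1031 between the untreated cultures, which lie in the same pair of sets.

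Genes that respond to the ligand and genes that differ in the receptor knockout were compared, with the control culture behind the knockout and the vehicle culture behind the ligand so that no array was shared. Across genes the knockout difference had Pearson r -0.066 with PDGF-BB at 12 h, -0.074 with PDGF-BB at 24 h and 0.098 with the 3-factor culture. With the untreated cultures exchanged, again with no shared array, these were -0.399, -0.499 and -0.456. Called genes in opposite directions numbered 65, 62 and 56, where independence would give 12.9, 10.7 and 16.1, and those in the same direction 31, 27 and 65, where independence would give 11.2, 9.12 and 16.3. With the untreated cultures exchanged, 26, 75 and 535 genes went in opposite directions, where independence would give 3.37, 8.72 and 117.03, and 4, 2 and 65 in the same, where independence would give 2.95, 7.44 and 104.62. For the 3 factors both comparisons lie within the authors' sets in the first version, while in the exchanged one both cross the sets, in opposite senses, so a difference between the sets would itself give opposite calls and a negative r there. For PDGF-BB the exchanged version sets the knockout against vehicle and PDGF-BB against the control culture. The PDGF-BB cultures lay between the untreated cultures in Sox9 and Pdgfra, among others. Such genes can give opposite differences and a negative r without a response to the ligand, so these values cannot show that knockout and ligand oppose each other. Sox9 and Inhba, named after their values were seen, were lower in the knockout culture and higher with the 3 factors against either untreated culture. Within the authors' sets, the 3-factor culture against vehicle and PDGF-BB at 24 h against the control culture shared 23 called genes in direction, Sox9 and Hbegf among those higher, and 17 were opposite, where independence would give 4.23 and 4.2, with Pearson r -0.05 across genes. With PDGF-BB at 12 h 18 were shared in direction and 7 opposite, where independence would give 1.79 of each, with r 0.08.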

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

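The test of further probes of the lower genes in the knockout hearts and the count of fibroblast markers there were chosen only after the result was seen. The other tests in this part were written down beforehand.

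Xist fell below detection in the knockout hearts, at least 10.3-fold, and rose by 1.56 in the knockout culture. A difference in direction between hearts and cultures was also seen for Prkar2b (1.14 and -2.57) and for the Y-linked Eif2s3y, at least 1.81-fold higher in the knockout hearts and at least 6.48-fold lower in the knockout culture. In the PDGF-BB cultures Nppa had 2.96 at 12 h and -2.23 at 24 h against the control culture, and Xist rose by 1.57 at 12 h and was at least 3.53-fold lower at 24 h against vehicle. The differences from the undetected levels themselves were -4.66, 1.05, -3.63 and -2.79, which measure no fold. With 1 array per group, none of these differences was tested. In both knockout comparisons Xist and the Y-linked Eif2s3y moved oppositely to each other, as pools with a different mix of sexes would give. Neither gene can therefore be credited to the knockout.

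The first pattern weighed is the 1031 genes called between the vehicle and the control culture, both untreated and wild type. Normalization alone is argued against, since 550 to 1086 genes were called under 3 other settings, and heart tissue or blood left in the cultures is argued against as the whole cause, since 67 genes (6.5%; 27 of the 326 higher and 40 of the 705 lower) were at least 1 higher in the control heart. The processing set cannot be told apart from the cultures: over these genes the difference between the 3-factor and the 24 h PDGF-BB culture, which lie in the same pair of sets and share no array with them, had a slope of 0.481, with 843 of 1031 in the same direction, and treatment differs in that pair too. A difference between pools or days of culture stays open and was not tested. The pools did differ in the Y-linked Eif2s3y, with a level of 5.79 in the vehicle culture and 7.95 in the control culture.

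The second pattern is the 41 lower genes of the knockout hearts, with Pdgfra, Sox9, Snai2 and Mfap4 among them. Of these, 3 of 41 (7.3%) lie on X or Y, so X- and Y-linked genes alone do not make up the pattern. The heart pools did differ in Xist and the Y-linked Eif2s3y. Autosomal genes that may differ with sex were not tested, so the count cannot decide on sex for the other genes. Noise of single probes cannot be told apart from a real decrease, because the 10 lower genes with another detected probe had a median of 0.447 in the direction of the call (9 of 10 in that direction), between the values set for either reading. Fewer mesenchymal cells, a biological explanation that the design allows, may also lower these genes. Below 0 lay 10 of 12 fibroblast markers, among them Pdgfra, a target of the knockout. But the markers were seen before this test, and lower levels per cell cannot be told apart from fewer cells in whole hearts.

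The third pattern is the 223 lower genes of the knockout culture. Less heart tissue or blood in that culture is argued against as the whole cause, since 50 genes (22.4%) were at least 1 higher in the control heart than in the control culture, although those include the lower cardiomyocyte and globin genes. Without such genes 177 of the 184 higher and 173 of the 223 lower genes remained. They were thus more frequent among the lower genes, and less heart tissue or blood may account for that part. Of the lower genes 10 of 223 (4.5%) lie on X or Y, so X- and Y-linked genes alone do not make up this pattern either. These culture pools too differed in Xist and Eif2s3y, and autosomal genes that may differ with sex were not tested. The loss of the receptors and the spread between untreated cultures stay open, since the control culture and the vehicle culture differed in more genes than the knockout and the control culture did.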

How the results depend on the processing

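The alternative that left out genes brighter in the heart was chosen after seeing the data; all others were planned. No paired analysis was possible because each group has 1 sample. Leaving out a replicate was possible only for the untreated pair, and is the choice of untreated culture below. Signal over background sets which genes can be called, since a gene under the detection limit on both arrays is never called. Over the 159 list medians, 154 kept their sign and side of the percentile limits with hearts and cultures normalized apart, 151 with median centring, 151 with offset 50, 149 without background correction, 147 with the mean of all probes, 139 of 151 with detection on both arrays, 124 without a detection filter and 65 of 68 with the authors' values, but 51 of 90 with the other untreated culture. Of 358 values of named genes, 264 to 358 kept direction and call under the alternatives that could be run on all, and 150 of 203 with the other untreated culture. Scaling moved the median over all genes by under 0.1 in each setting. The authors' values were not run across their sets.

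The number of called genes moved by over 1.5 times as follows, and the cause was not tested. Without background correction it was 16 in the knockout hearts (59 as reported), 224 in the knockout culture (407), 311 with PDGF-BB at 12 h (659), 233 at 24 h (553), 621 with the 3 factors (950), 783 for the 3 factors against PDGF-BB (1307) and 550 between the untreated cultures (1031). With offset 50 the same comparisons gave 16, 215, 293, 219, 602, 752 and 516. With detection required on both arrays there were 25 in the hearts, 399 at 12 h, 321 at 24 h, 846 for the 3 factors against PDGF-BB and 678 between the untreated cultures; fewer genes can then be called. With the mean of all probes there were 32 in the hearts, 258 in the knockout culture, 398 at 12 h, 328 at 24 h, 818 for the 3 factors against PDGF-BB and 650 between the untreated cultures. Median centring gave 37 in the hearts, and between the untreated cultures 1083, with 41.9% of them higher in place of 31.6%. The authors' values gave 13 in the hearts, 244 in the knockout culture and 557 with the 3 factors.

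With the other untreated culture as control there were 1426 called genes in the knockout culture, 54 at 12 h, 119 at 24 h and 1633 with the 3 factors. With the mean of both untreated cultures there were 623 in the knockout culture, 72 at 12 h and 55 at 24 h. Taking both untreated cultures as a group of 2, limma called 0 genes in the knockout, 12 h, 24 h and 3-factor cultures, with 386, 25, 19 and 749 at an unadjusted p under 0.05, on 1 residual degree of freedom. Leaving out genes at least 1 higher in the heart gave 350 genes in the knockout culture, 610 at 12 h, 515 at 24 h, 851 with the 3 factors, 1196 for the 3 factors against PDGF-BB and 964 between the untreated cultures, all within 1.5 times.

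Overlaps moved too, and the cause was not tested. The 8 genes shared by knockout hearts and culture became 4 without background correction, 4 with offset 50, 3 with the authors' values, 5 with detection on both arrays and 5 with the mean of probes. Genes opposite between the knockout culture and PDGF-BB at 12 h (65) became 28 without background correction, 26 with offset 50, 27 with detection on both arrays, 41 with the mean of probes and 26 with the untreated cultures exchanged; at 24 h (62) they became 25, 23, 29 and 37 under the first 4 of these. For the 3 factors (56) they became 31, 30, 27 and 37 under the same 4, 31 with the authors' values and 535 with the cultures exchanged. The 413 genes shared by 12 h and 24 h became 184, 172, 245 and 247 under those 4. The 83 list medians outside the percentile limits stayed within 1.5 times.

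These results reversed with the other untreated culture as control, and the cause was not tested. In the knockout culture they were the medians of immediate-early (-0.22), cytokine (0.31) and stress genes (-0.14), and Pdgfra (0.28), Krt19 (-0.70) and Saa3 (5.16). With PDGF-BB at 12 h they were the medians of matrix (-0.031), immediate-early (0.11), epicardial (-0.27), fibroblast (-0.13), smooth muscle (0.30) and macrophage genes (-0.13), and Adgre1 (-1.13), Csf1r (-0.40), Krt19 (0.53), Lyz2 (-0.22) and Saa3 (-0.32). At 24 h they were the medians of epicardial (-0.23), smooth muscle (0.40), erythroid (1.81) and macrophage genes (-0.30). With the 3 factors they were the medians of glycolysis (-0.12), stress (0.073), smooth muscle (0.55), endothelial (0.006) and macrophage genes (-0.03), and Adgre1 (-1.84), Des (0.54), Lyz2 (-0.55), Myh11 (0.98) and Ramp2 (0.031). Krt19 at 12 h and Myh11 were set against a level without detection in the control culture, and Ramp2 was not detected in the 3-factor culture, so these 3 are not measured reversals. With the 3 factors another Adgre1 probe kept its sign, with 1.88 against vehicle and 0.32 against the control culture. At 12 h another Csf1r probe kept its sign, with 0.79 and 0.32. With detection on both arrays, the medians of cardiomyocyte genes at 12 h (-0.018), endothelial genes with the 3 factors (0.18) and glycolysis genes for the 3 factors against PDGF-BB (0.10) reversed. Without a detection filter, those of endothelial genes in the knockout culture (-0.004) and retinoic acid genes for the 3 factors against PDGF-BB (-0.10) did, and with median centring Rif1 in the knockout hearts (-0.40).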

Other observations

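The comparison of the vehicle culture with the control heart and its values were chosen only after the data were seen; both arrays are in the same normalization set.

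Set against the whole control heart, the vehicle culture had little RNA of heart muscle and vessels. Of 24 measured cardiomyocyte genes 23 were lower, with a median of -6.86 (-6.42 with undetected members at their bound): cardiac actin Actc1 (-8.93), the myosin light chain Myl3 (-8.54) and Nppa (-8.42) fell, and Csrp3 and Actn2 were at least 494-fold and at least 413-fold lower. All 16 measured endothelial and endocardial genes were lower, with a median of -4.75 (-4.04 with undetected members at their bound), among them Plvap and Emcn, at least 93.5-fold and at least 105-fold lower. Of 8 erythroid genes 7 were lower. In all, 2994 of 9661 measured genes were called, 1550 higher and 1444 lower.

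Epicardial genes were higher in the culture for 9 of 12 measured members, with a median of 2.33 (1.30 with undetected members at their bound): the mesothelial genes Upk1b (4.63) and Msln (at least 36.1-fold higher) and Tcf21 (3.05) rose. Fibroblast genes were higher for 9 of 13, with Thy1 at 5.76 and Pdgfra at 2.79, and collagen and extracellular matrix genes for 17 of 30, with Col8a1 at least 112-fold higher. Macrophage and leukocyte genes were higher for 14 of 15, with a median of 3.07, the adaptor Tyrobp at 3.96 and complement C1qc at 3.29. Cytokine and chemokine genes were higher for 11 of 12 and stress genes for 12 of 19, and glycolysis and hypoxia genes lower for 11 of 25, with Pfkl at -3.25 (-0.19 for another detected probe). In the other direction, 4 glycolysis and hypoxia genes rose, and 4 matrix, 1 epicardial, 1 fibroblast and 1 cytokine gene fell. Smooth muscle actin Actg2, the stress gene Nupr1 and Snai1 were at least 161-fold, at least 111-fold and at least 5.77-fold higher.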
